A study of Drosophila melanogaster with 2 samples.

How the data were processed

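ChIP-seq was done on whole Drosophila melanogaster embryos of 0 to 24 h, pooled from both sexes, of a transgenic line expressing the RB isoform of sima with GFP at its C terminus. Per the labels, chromatin was sonicated to fragments of 200 to 800 bp and immunoprecipitated with an antibody against GFP. The 2 samples are biological replicates 1 and 2 of 1 group, and no control sample was analysed here.

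The 8 region lists used were deposited in narrowPeak layout. On each of the builds dm6 and dm3, there was a relaxed list of 30000 regions for each replicate, one for the pooled reads of both, and a list thresholded on the irreproducible discovery rate (IDR). Per the accompanying text files, the authors called each relaxed list against 1 control file. In every list the authors deposited a signal value per region, as the peak caller gave it; its scale and any scaling for depth are not given in the sources used here, so signals were compared by rank, by ratio to the list's median or as log2 differences within a list. The q values were deposited as -log10 q by the peak caller and were used for no comparison. The p column of the layout held no p values. The peak caller, the IDR threshold and the software versions are not given in the sources used here. Read numbers are not given either, so the depth per sample is unknown and no precision from depth can be given. The dm6 IDR list was checked to be exactly the 1272 regions of the pooled list with the highest signal, and the dm3 list the top 1248.

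All comparisons used dm6 and were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Sequence came from the Release 6 genome and gene models from Ensembl release 115 (BDGP6.54). Positions are those of the deposited lists for regions and of the annotation for genes. A summit was near a start site when it lay within 500 bp of the first base of any annotated transcript. A protein-coding gene was counted as bound when an IDR summit lay within 500 bp of any of its start sites, and the background was the 13945 protein-coding genes on the 6 arms with IDR peaks. Annotation classes were assigned to the summit base in the order coding sequence, 5' UTR, 3' UTR, intron and intergenic.

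Replicate overlap was the share of the top 1272 regions by signal of one replicate with a summit within 100 bp of a top region of the other, beside the share after a shift of 10000 bp. Correlations were across IDR peaks matched to the nearest summit within 100 bp in each replicate, with an interval from 1000 bootstrap draws of peaks, and no p was computed. The share of summits near start sites was compared with 1000 circular shifts of all summits along each arm (permutation test, one-sided; two-sided for the annotation classes). The share of peaks on X was compared with its share of the length of the major arms by an exact binomial test. The 22 gene lists were compared with all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists at a threshold of 0.05; odds ratios had 0.5 added to each cell. Words were counted on either strand within 50 bp of each summit and in 1 window of the same size centred 500 bp to a side chosen at random with a fixed seed. Peaks with the word at one place only were compared by the exact McNemar test, two-sided, adjusted over the 11 fixed words or over all 2080 words of 6 bases. Differences in rank, in median log2 signal and in G+C content were tested with 100000 permutations, two-sided. Peaks and genes, not samples, are the units of these tests.

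The comparisons, the gene lists, the fixed words and the alternatives were chosen before the data were examined. The exceptions, chosen after the data were seen, are the G+C content and its matched windows, the G+C classes of words, the signed distances to start sites, the values by rank, the overlap at other numbers of regions, the annotation classes under the alternatives, the region density over sima, 6 further gene lists and the tRNA genes. All 335 members listed by symbol were found in the annotation, 7 of them under a newer symbol that was looked up after the data were seen, by gene identity alone. Matched windows were drawn 10 times for each peak at least 1000 bp from any IDR peak, with a G+C count within 1 base. For a promoter peak they lay at the same signed distance from another start site, and for other peaks on the same arm, over 500 bp from any start site.

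Named genes follow a rule fixed beforehand. It takes the nearest protein-coding gene of the 10 strongest peaks, every member of the HIF pathway and hypoxia target lists, the 5 strongest promoter peaks with the hypoxia core, and the sima gene. For each other list that passed, and for glycolysis and tracheal genes, it takes the 4 bound members with the strongest peak and the first 2 unbound members by alphabet. Case was ignored in that order, which was settled after the values were seen. This gave 44 genes. Bound members of other lists with few bound genes, and Pgk, Gpdh1, PyK, Tpi and Pfk, are named for completeness and were chosen after their values were seen.

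The word test, the gene list test, the shift test of the share near start sites and the permutation test of signal were tested on simulated data; the other tests were not. With no word planted, 0 of 2080 words passed in 1272 simulated windows, and a planted word ranked 1 by p. Those windows had the same base composition at centres and flanks, unlike the real ones, so this check does not cover differences in composition. In 200 simulated sets of bound genes, any of the 22 lists passed in 9 sets when nothing was planted, and a list with a raised share passed in 200. The shift test gave a permutation p of 0.438 for 1250 uniform positions and 0.00498 when part of them was placed at start sites. The permutation test of signal passed in 14 of 200 simulated sets of 1272 peaks with no difference, and in 200 sets with 0.2 added to one class.

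Alternatives were the stronger 636 IDR peaks, the 1272 strongest nuclear regions of each replicate alone, the dm3 lists, other matching distances (50 and 250 bp) and numbers of regions, and start-site distances of 250, 1000 and 2000 bp. For gene lists they were the gene body with 1000 bp upstream, genes with a start region of their own, and genes matched on their number of start sites (10000 draws). For words they were windows of 25 or 100 bp to either side, flanks 1000 bp away, each version of the core, promoter or other peaks alone, and the matched windows. The density on X in dm3 was not computed for want of arm lengths. With 2 samples in 1 group, no comparison between groups, test of outlying samples or regrouping of samples was possible.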

Results

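Chromatin immunoprecipitation followed by sequencing mapped the binding of Sima, the fly ortholog of the hypoxia-inducible factor HIF-1alpha, in whole Drosophila melanogaster embryos. The embryos came from a transgenic line that carries the RB isoform of sima fused to GFP, were 0 to 24 h old, and were pooled from both sexes. The immunoprecipitation used an antibody against GFP, and the labels name Sima as its target. There were 2 biological replicates of 1 group, and no second group or control sample was analysed here. No oxygen level or hypoxia treatment is among the sample traits used here, so binding under hypoxia was not compared with binding at normal oxygen. The deposited values were lists of enriched regions, each with a signal value from the peak caller. Read numbers are not given in the sources used here, so the depth of each library is unknown. Intervals below cover counting error over peaks or genes only.

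The list thresholded by the irreproducible discovery rate (IDR) held 1272 peaks on the dm6 build with a median width of 396 bp. There were 248 peaks on 2L, 234 on 2R, 252 on 3L, 300 on 3R, 231 on X and 7 on the small chromosome 4. The signal of these peaks ran from 59.0 to 760. The list equalled the 1272 strongest of the 30000 regions called on the pooled reads, so the threshold set its length. Signals are given below as the rank in that pooled list and as the ratio to the median signal of each replicate's own list.

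The strongest peaks lay at or near Ugalt, CG14100, cbt and px, and each was found in both replicates. The first, at X 2703717 to 2704059, had its summit at -37 bp from the start site of Ugalt, which encodes a UDP-galactose transporter, with a ratio of 31.3 ± 13.0 (SD, n = 2). The second, at 3L 19590459 to 19590786, lay at -95 bp from CG14100 with a ratio of 30.6 ± 13.0 (SD, n = 2). The third, at 2L 480924 to 481261, lay outside cbt, in an intron of another gene, and had a ratio of 28.1 ± 9.59 (SD, n = 2). Its nearest protein-coding start site, with the summit at -1377 bp, was that of cbt, which encodes a zinc-finger transcription factor. The fourth, at 2R 22514156 to 22514448, lay in an intron at -213 bp from a start site of px, a gene required for wing vein patterning, with a ratio of 27.0 ± 6.56 (SD, n = 2). Next by rank came an intronic peak 1030 bp downstream of an internal start site of CG11050 (2L 6612543 to 6612885; ratio 23.3 ± 4.01, SD, n = 2) and peaks upstream of mRpS10 and mRpL41, which encode mitochondrial ribosomal proteins. The mRpS10 peak (3R 15229376 to 15229672) had a ratio of 23.4 ± 8.53 and the mRpL41 peak (2R 15217585 to 15217909) one of 21.7 ± 7.76 (SD, n = 2 each). The last of the 10 strongest lay in the 5' UTR of Chro, a chromodomain protein gene (3L 22878751 to 22879070; 20.9 ± 11.1), in an intron near the kinase gene Lk6 (3R 11760905 to 11761178; 19.5 ± 4.78) and in an intron near the Polycomb group gene ph-p (X 2137207 to 2137518; 19.5 ± 7.24; SD, n = 2 each). Replicate 2 ranked these 10 peaks between 1 and 12, and replicate 1 between 11 and 26. The 10 highest ranks of replicate 1 were regions of the mitochondrial genome.

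How far the replicates located the same sites was asked from the top 1272 regions of each. Of these, 676 had summits within 100 bp of each other (53.1%, Wilson 95% interval 50.4 to 55.9), against 4 (0.314%) after one replicate was moved by 10000 bp. Among the 100 strongest of each replicate, 60 were shared, and among all 30000, 6802 (22.7%, against 6.35% after the move). The list of replicate 1 held 14 mitochondrial regions, ranked 1 to 33, and that of replicate 2 held none, so these could not be shared. Of the 1272 IDR peaks, 1186 had a matching region in both replicates, and 702 were among the top 1272 of both. Across the 1186 matched peaks, which are not independent replicates, Spearman's rho of the signal was 0.412 (bootstrap 95% interval 0.357 to 0.461) and Pearson's r of its log2 was 0.547. Across the top 20000 pooled regions, 6751 were matched in both replicates, with rho 0.509 and r 0.698. With 2 samples no test across samples was possible.

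Sima peaks lay close to transcription start sites. The summits of 693 of the 1272 peaks (54.5%, Wilson 95% interval 51.7 to 57.2) were within 500 bp of an annotated start site, against 13.6% ± 1.12 (SD over 1000 circular shifts of the summits along each arm; highest 17.0%). The one-sided permutation p was 0.000999, the smallest the shifts can give. Of the 653 summits within 500 bp of a protein-coding start site, 534 lay upstream and 119 at or downstream of it, with a median position of -117 bp. The 300 bp just upstream of start sites held 459 summits. By annotation class, 5' UTRs held 9.75% of summits against 3.08% of shifted ones, introns 47.9% against 42.1% and intergenic sequence 40.3% against 32.8%. Coding sequence held 5 summits (0.393% against 17.1%), and 3' UTRs held 1.65% against 4.95%. Each of these class shares had a two-sided permutation p of 0.002, the smallest possible. The excess in intergenic sequence was lost with the strongest regions of replicate 1 alone (35.0%, permutation p = 0.272).

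**Figure D1:**
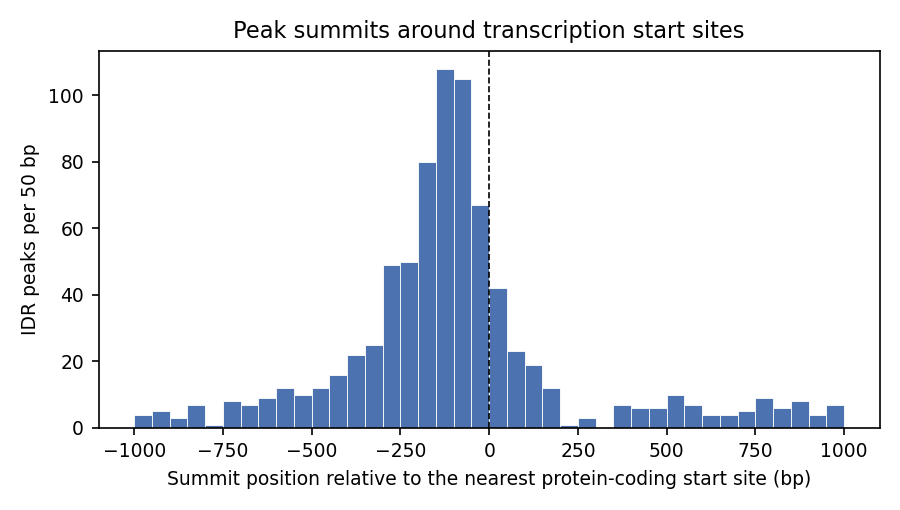
Number of IDR peaks per 50 bp (vertical axis) by the position of the summit relative to the nearest protein-coding start site in bp (horizontal axis, negative upstream, drawn to 1000 bp on either side). The peaks gather upstream of the start site, with 459 summits between -300 and -1 bp and 119 between 0 and 500 bp.

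Because the embryos were of both sexes, the X chromosome was at a lower copy number than the autosomes in the pool. Of the 1265 peaks on the 5 major arms, 231 lay on X (18.3%, Wilson 95% interval 16.2 to 20.5), and X makes up 17.8% of their length. The density on X was 1.03 times that on the autosomes, a difference that was not detectable (exact binomial test, two-sided, p = 0.633). The direction turned, without passing the threshold, among the stronger 636 peaks (0.954) and with replicate 1 alone (0.896).

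Genes for cytoplasmic ribosomal proteins were the most often bound of the 22 gene lists fixed beforehand. A peak summit lay within 500 bp of a start site for 44 of 92 ribosomal protein genes (47.8%, Wilson 95% interval 37.9 to 57.9), against 5.95% of other protein-coding genes (log2 odds ratio 3.86, Fisher's exact test, two-sided, adjusted p = 1.45e-27 over the 22 lists). The strongest were RpS27 (3R 25245955 to 25247514; rank 32, ratio 12.1 ± 3.46, SD, n = 2) and RpL32 (3R 30045229 to 30046161; rank 39, ratio 11.3 ± 3.49, SD, n = 2). They were followed by RpL7 (2L 10201004 to 10202321; rank 52, ratio 10.1 ± 4.19, SD, n = 2) and RpL23A (3L 1666288 to 1668654; rank 85, ratio 8.45 ± 3.0, SD, n = 2). Not all members were bound: the best region at RpL10 had rank 26450, and no region of the pooled list lay within 500 bp of a start site of RpL10Aa. The 92 members include genes with symbols ending in -like, which were counted as ribosomal protein genes. The list passed with each replicate alone and at every distance tried. Some bound members share a start region with another gene. Among genes with a start region of their own, 23 of 55 members were bound and the list passed (log2 odds ratio 4.32, Fisher's exact test, adjusted p = 8.72e-18). The background at these promoters in embryos without the tagged protein was not analysed here.

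The glycolysis list, which holds textbook targets of HIF-1 in mammals, was the other list that passed. Its members are called glycolytic genes here, though some, such as Gpdh1 and fbp, encode enzymes outside glycolysis proper. Of 17 genes, 6 were bound (35.3%, Wilson 95% interval 17.3 to 58.7) against 6.19% of other genes (log2 odds ratio 3.10, Fisher's exact test, two-sided, adjusted p = 0.00429). The bound genes were Gapdh2 (glyceraldehyde-3-phosphate dehydrogenase), Hex-A (hexokinase), Ldh (lactate dehydrogenase), Eno (enolase), Pgk (phosphoglycerate kinase) and Gpdh1 (glycerol-3-phosphate dehydrogenase). The peak at -161 bp from Gapdh2 (X 15868145 to 15869661) had rank 97 and a ratio of 7.57 ± 0.386 (SD, n = 2), and that at -174 bp from Hex-A (X 9585675 to 9589813) rank 113 and a ratio of 7.05 ± 0.127 (SD, n = 2). Ldh (3L 6259105 to 6262694) followed at rank 380 with a ratio of 3.95 ± 0.722 (SD, n = 2), and Eno (2L 1724768 to 1729636) at rank 724 with 2.95 ± 0.932 (SD, n = 2), though Eno was not bound with replicate 1 alone or among the stronger 636 peaks. The 11 unbound members had their best regions at rank 1628 (PyK, pyruvate kinase), 1682 (Tpi, triosephosphate isomerase), 2160 (Pfk, phosphofructokinase) and from 6067 down, with Ald1 (aldolase) at 6832 and fbp (fructose-1,6-bisphosphatase) at 19519. With replicate 2 alone, Pgk and Gpdh1 (ranks 1639 and 1486 there) were not bound. With replicate 1 alone 6 genes were bound, Tpi (rank 741 there) in place of Eno. The call for this list ended among the stronger 636 peaks (3 genes; log2 odds ratio 2.84, adjusted p = 0.185) and with replicate 2 alone (4 genes; 2.26, adjusted p = 0.139; Fisher's exact tests). It also ended when genes were matched on their number of start sites (2.00, permutation adjusted p = 0.121). Only 3 of the bound members had a start region of their own, out of 9 such members (3.81, Fisher's exact test, adjusted p = 0.0397).

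**Figure D2:**
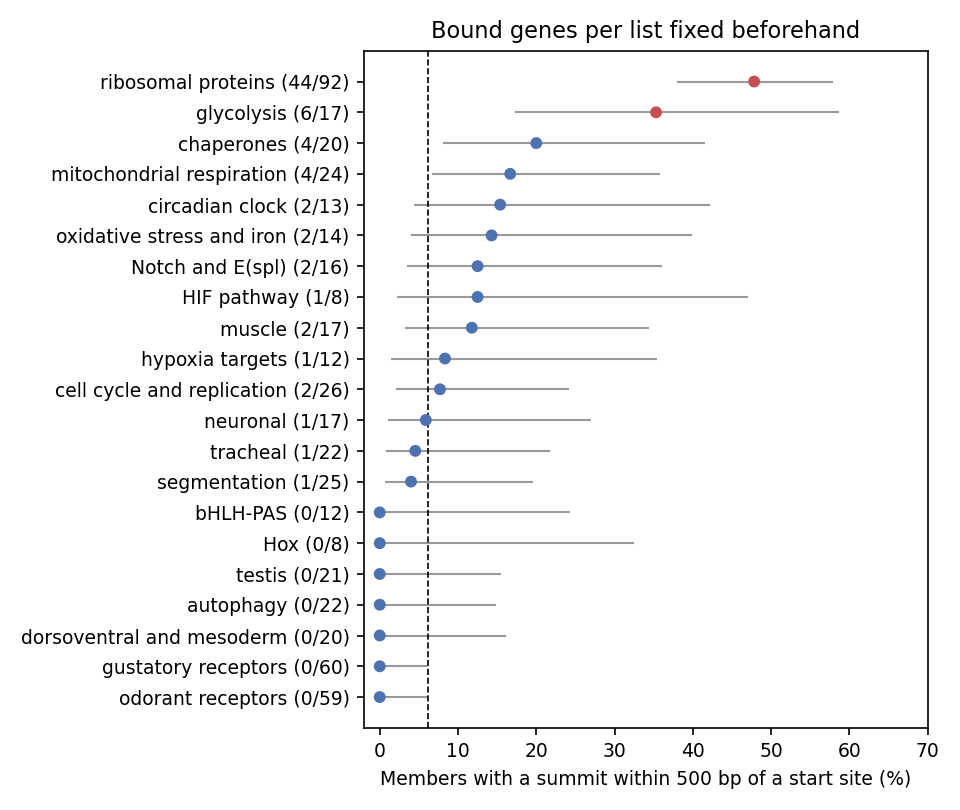
Percentage of the members of each gene list given in the text with a peak summit within 500 bp of a start site (horizontal axis; points, with Wilson 95% intervals as lines, and bound/all members beside each name). Red points mark the lists past the threshold, ribosomal proteins at 47.8% and glycolysis at 35.3%, and the dashed line is the share among all 13945 protein-coding genes, of which 868 were bound.

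The HIF pathway itself and the list of hypoxia targets did not pass in these embryos, which were not compared with embryos at another oxygen level. Of 8 pathway genes, 1 was bound: EloB, which encodes elongin B, a subunit of the ubiquitin ligase that holds Vhl (rank 1263, ratio 2.49 ± 0.556, SD, n = 2). The list had a log2 odds ratio of 1.59 (Fisher's exact test, adjusted p = 0.68), and EloB was not bound with replicate 1 alone. EloB shares its start region with another gene, so its peak cannot be assigned to EloB alone. Of the 5 pathway genes with a start region of their own, 0 were bound. Below the IDR threshold, regions within 500 bp of a start site had rank 2204 at sima, 5306 at Cul2, 6836 at Vhl, 8090 at Hph (the prolyl hydroxylase that marks Sima for degradation) and 26326 at EloC. The pooled list held none at tgo, which encodes the DNA-binding partner of Sima, or at Roc1a. Of 12 hypoxia targets, Ldh alone was bound (log2 odds ratio 0.97, Fisher's exact test, adjusted p = 0.845). With 1 replicate alone 2 of 12 were bound, without passing (log2 odds ratio 1.77 with replicate 2 and 2.02 with replicate 1; exact adjusted p = 0.503 and 0.498). The next were Thor, the translation inhibitor 4E-BP (rank 1492, ratio 2.02 ± 1.25, SD, n = 2), ERR, the estrogen-related receptor (rank 1893), and scyl, a TOR pathway inhibitor (rank 2181, ratio 1.44 ± 0.242, SD, n = 2). The remaining members had ranks of 4337 (InR), 7168 (bnl), 7717 (BNIP3), 7843 (chrb), 8090 (Hph) and 9397 (Pdk), or no region (Hsf and btl). Thor and the start site of sima were counted as bound with replicate 1 alone, and ERR with replicate 2 alone. The intervals of both lists were wide (2.24 to 47.1% of members for the pathway and 1.49 to 35.4% for the targets), so a share as large as that of the glycolytic genes is not excluded for either list.

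Among tracheal genes, which build the oxygen-supplying airways, 1 of 22 was bound: pyd, a cell junction gene (rank 976, matched within 100 bp in replicate 1 at rank 855 and not in replicate 2, though its start sites counted as bound with either replicate alone). The FGF gene bnl and its receptor gene btl were unbound, and the list did not differ detectably from other genes (log2 odds ratio 0.07, Fisher's exact test, adjusted p = 1). Its share of bound members was the lower one (4.55% against 6.23%), so the positive sign of the log2 odds ratio comes from the 0.5 added to each cell. Chaperone genes were bound in 4 of 20 cases (Hsp26, Hsp27, Hsp83 and Hsc70-4; log2 odds ratio 2.04) and mitochondrial respiration genes in 4 of 24 (mAcon1, blw, COX5A and ND-51; 1.73), each with an adjusted p of 0.215 by Fisher's exact test. Circadian clock genes had 2 of 13 bound (sgg and slmb), oxidative stress and iron genes 2 of 14 (the ferritin genes Fer1HCH and Fer2LCH, which share 1 peak), Notch and E(spl) genes 2 of 16 (numb and E(spl)m3-HLH) and cell cycle genes 2 of 26 (RnrS and dpa). None of these 4 lists passed, with adjusted p between 0.526 and 0.874 by Fisher's exact test. The result of 1 further list, which did not pass, is not given here. For genes of single tissues, 2 of 17 muscle genes (sls and Msp300), 1 of 17 neuronal genes (elav) and 1 of 25 segmentation genes (bcd) were bound. There were 0 of 21 testis, 0 of 20 dorsoventral and mesoderm, 0 of 8 Hox, 0 of 12 bHLH-PAS and 0 of 22 autophagy genes, with adjusted p of 0.572 to 1 for these 8 lists by Fisher's exact test. No peak lay near any of 59 odorant receptor genes (Wilson 95% upper bound 6.11%) or 60 gustatory receptor genes (6.02%), and the adjusted p was 0.215 for each by Fisher's exact test. At a distance of 2000 bp, the odorant and gustatory receptors were bound less often than other genes (0 bound, adjusted p = 0.0328 each by Fisher's exact test).

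The hypoxia response element core RCGTG, the textbook site of HIF heterodimers, was less frequent at summits than beside them. It stood within 50 bp of the summit, on either strand, in 169 of 1272 peaks (13.3%, Wilson 95% interval 11.5 to 15.3), and in 270 equal windows centred 500 bp away (21.2%, 19.1 to 23.6). The ratio was 0.626 (exact McNemar test, two-sided, p = 1.9e-07; adjusted p = 1.05e-06 over 11 words). The 5 strongest promoter peaks with the core lay at CG1888 (rank 20, ratio 14.0 ± 6.02), RpS27, Elp5, an Elongator subunit gene (rank 45, ratio 10.4 ± 3.35), RpL7 and eEF1gamma, a translation elongation factor gene (rank 81, ratio 8.32 ± 2.92; SD, n = 2 each). None of the 10 strongest peaks carried it. Of the 44 ribosomal protein peaks 16 did (36.4%), against 24.1% ± 6.17 (SD over 10 draws, highest 36.4%) of windows matched to them (median exact p = 0.237). Against windows matched to the summits in G+C content and position relative to start sites, the difference was lost (13.5% ± 1.15, SD over 10 draws; log2 ratio -0.018, median exact p = 0.529), and with ACGTG alone the call ended (log2 ratio -0.38, exact p = 0.065; with GCGTG alone -0.95, exact p = 1.04e-07). Peaks with the core had a mean rank of 685 and those without it 629, a difference of 55.8 that did not pass (permutation test, two-sided, p = 0.0667) and was 25.4 with replicate 2 alone, 22.2 with replicate 1 alone and 14.4 among the stronger 636 peaks.

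Among all 2080 words of 6 bases, 287 were more frequent at summits than in flanks and 490 less frequent at an adjusted p under 0.05 (exact McNemar tests). The words with the smallest p were rich in A and T: TTAAAA stood at 398 summits against 163 flanks, and all of the 20 words with the smallest p among those gained held at most 1 G or C. The median ratio fell with the number of G and C bases, from 1.78 for words with 0 to 0.352 for words with 6. Of 16 words holding the core, 0 were gained and 4 were lost, with a median ratio of 0.684. Relative to words with the same number of G and C, that direction turned (log2 ratio 0.21). Among the words fixed beforehand, TATCGA, part of the DNA replication-related element found at housekeeping promoters, was gained 2.17-fold (100 against 46 peaks, adjusted p = 2.5e-05 by the exact McNemar test over 11 words). Its gain did not pass away from promoters (27 peaks, log2 ratio 0.23, exact p = 0.672) or against matched windows (log2 ratio 0.40, median exact p = 0.0966). Yet 7.86% of summits held TATCGA, above all 10 matched draws (5.97% ± 0.562, SD, highest 6.76%). At promoter peaks the shares were 10.5% against 7.63% ± 1.06 (SD, highest 9.38%), so the matched windows leave this gain undecided. TGATAA, a site of GATA factors, was gained 1.45-fold (113 against 78, exact adjusted p = 0.021), but not against matched windows (8.88% against 9.13% ± 0.64, SD over 10 draws; median exact p = 0.808). ACACAC (59 against 131, exact adjusted p = 7.58e-07) and GAGAGA, the site of GAGA factor (42 against 71, exact adjusted p = 0.0152), were less frequent at summits. The E-box CACGTG stood at 14 summits and 14 flanks, and CAGGTA, CAGCTG, TACGTG, GACGTG and TGACTC did not pass (exact adjusted p of 0.11 to 0.592).

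The sequence at Sima summits was on average rich in A and T. The G+C content within 50 bp of the summit was 34.5% ± 8.37 (SD over 1272 peaks), against 43.4% ± 10.4 in the flanks. The difference was -8.94 points (SE 0.384), and 930 of the peaks had the lower value at the summit (permutation test, two-sided, p = 1e-05, the smallest possible). It was -10.2 points at the 693 promoter peaks and -7.46 points at the other 579. Down the pooled list, the share of summits near start sites fell from 56.9% in ranks 1 to 636 to 20.5% in ranks 20001 to 30000. The G+C content went from 33.7% to 42.5% and the share with the core from 12.3% to 19.6% over the same ranks. This comparison of composition was chosen after the data were seen.

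**Figure D3:**
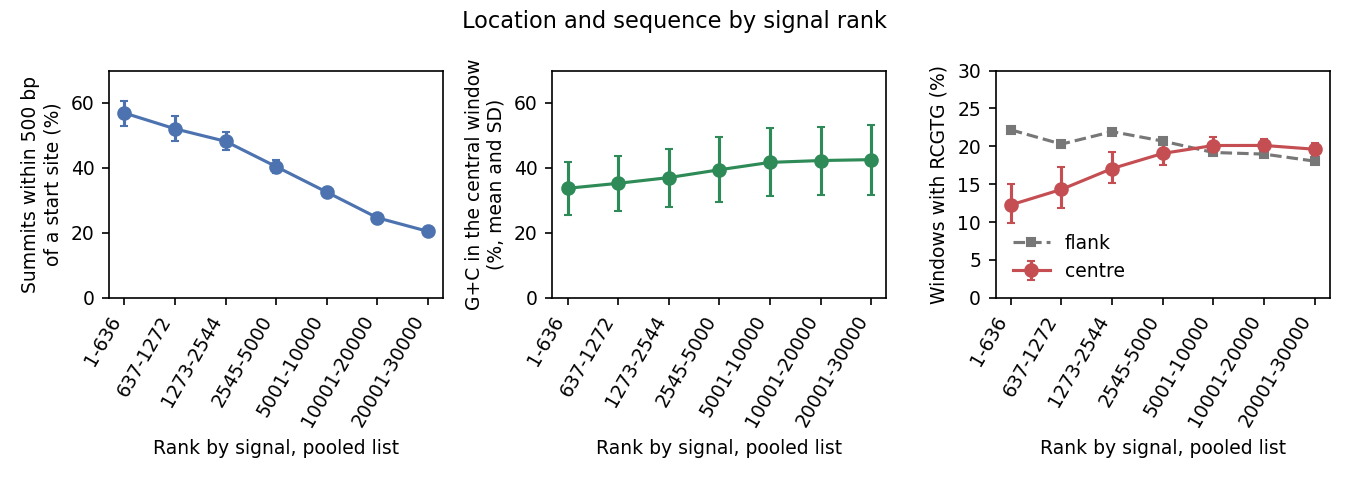
Share of summits within 500 bp of a start site (left, %, Wilson 95% intervals), G+C content within 50 bp of the summit (middle, %, mean and SD over regions) and share of windows with RCGTG (right, %; red, summits with Wilson 95% intervals; grey, flanks without intervals) by rank in the pooled list (horizontal axes). From the strongest to the weakest regions the promoter share goes from 56.9% to 20.5%, the G+C content from 33.7% to 42.5% and the core from 12.3% to 19.6%.

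Promoter peaks and other IDR peaks did not differ detectably in strength in the pooled list. The median log2 signal of the 693 promoter peaks was 0.05 higher than that of the 579 others (permutation test, two-sided, p = 0.176). In replicate 2 the 669 matched promoter peaks were higher by 0.20 (permutation p = 1e-04), and in replicate 1 the difference was -0.0026 (675 peaks, permutation p = 0.938). The strongest regions of replicate 2 alone gave 0.14 (permutation p = 0.00109), and wider promoters gave 0.12 at 1000 bp and 0.17 at 2000 bp (permutation p = 0.00253 and 0.00014), each past the threshold.

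The sima gene itself (3R 30058311 to 30121798, 63488 bp) was examined because the transgene expresses its RB isoform. It held 2 IDR peaks, both intronic and without the core, with summits at 30061282 (rank 157, ratio 6.36 ± 1.60, SD, n = 2) and 30092833 (rank 264, ratio 4.98 ± 1.72, SD, n = 2). The pooled list had 34 regions over the gene, or 53.6 per 100 kb against 22.4 over the genome, and the replicates had 32 and 33. Of 322 genes of similar length, 4.97% held as many pooled regions. RpL32, with the second strongest ribosomal protein peak, lies 12149 bp from sima. On the other side of sima lies Tpi (3R 30132981 to 30134599), the glycolytic gene counted as bound with replicate 1 alone. How far the transgene's own sima sequence reaches, and whether it holds RpL32 or Tpi, is not given in the sources used here. The signals at RpL32 and Tpi were thus not separated from any extra copies.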

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

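One signal lay outside the regions compared, on the mitochondrial genome, and it was looked at only after the data were seen. The dm6 list of replicate 1 held 14 mitochondrial regions between positions 1388 and 14438, and those of replicate 2 and of the pooled reads held 0. Their signal ran from 166 to 1761, they ranked between 1 and 33 in replicate 1, and they filled its 10 highest ranks. On dm3, replicate 1 held 3 such regions, the pooled list 1 and replicate 2 held 0. No control sample was analysed here to give their background level.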

How the results depend on the processing

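The matched windows, the comparison of words at equal G+C, the annotation classes under other settings and the 6 added lists were tried only after the data were seen. Over 123 alternatives of 17 main results, 91 kept direction and side of the threshold (or stayed within the error or count range), 5 lost the call, 3 gained one, 15 moved and 9 changed direction. Of 37 alternatives of other values, 34 were the same and 3 lost the call. Of 384 alternatives for named genes, 21 changed whether the start site was bound. The strongest regions of the pooled list are the IDR list itself, so that setting changed nothing. It is included in the counts above, where it was the same by construction and is no evidence of stability. The X density on dm3 was not run. The share near start sites passed under all its alternatives, as did the ribosomal protein list. Read depth is unknown, so what it limits cannot be stated.

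Among the stronger peaks (636 by construction), rho was 0.466, the X density ratio 0.954, 1 list passed, and the log2 odds ratio was 2.84 for glycolysis and -0.61 for tracheal genes. Matching within 50 bp gave an overlap of 41.2% and rho of 0.469, matching within 250 bp an overlap of 59.6%, and 2544 regions an overlap of 44.3%. The signal difference was 0.12 at 1000 bp and 0.17 at 2000 bp, with tracheal genes at -0.21 and -0.58. At 2000 bp 4 lists passed, as did 4 with gene bodies. Matched on the number of start sites, 1 list passed, with glycolysis at 2.00, hypoxia targets at -0.073 and tracheal genes at -0.75. The HRE core had a log2 ratio of -0.38 with ACGTG alone and -0.018 against matched windows. Words of 6 bases gained and lost numbered 185 and 282 in promoter peaks and 81 and 74 in other peaks, which are fewer peaks by construction. Words with the core stood at 0.21 relative to words of the same G+C number.

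Leaving out each replicate gave 0.896 to 1.11 for the X density ratio, 0.040 to 0.14 for the signal difference, 1 to 2 lists, 2.26 to 3.27 for glycolysis and -0.0058 to 0.24 for tracheal genes. Apart from the smaller sets named, the cause was not tested.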

Other observations

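The added gene lists, the tRNA genes, the matched windows, the housekeeping test for glycolysis under other sets of peaks and the test on the sima gene were chosen after the data were seen. Of 111 cuticle protein genes, which build the larval and adult exoskeleton, 0 were bound against 6.27% of other genes (log2 odds ratio -3.90, Fisher's exact test, adjusted p = 0.00757 over the 6 added lists). The other 5 did not pass. Translation factor genes were bound in 7 of 51 cases (among them eIF6 at rank 74 and eEF1gamma at rank 81; exact adjusted p = 0.112), aminoacyl-tRNA synthetase genes in 4 of 32 (ThrRS, IleRS, ArgRS and SerRS; 0.27) and mitochondrial ribosomal protein genes in 7 of 73 (0.332). The latter include 4 of the stronger peaks, at mRpS10 (rank 6), mRpL41 (rank 7), mRpS23 (rank 29) and mRpL23 (rank 35). Proteasome genes were bound in 2 of 32 cases (Rpn5 and Rpn3; exact adjusted p = 1) and serine protease genes in 0 of 26 (0.487). These single genes were chosen after their values were seen.

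The hypoxia core was less frequent at summits than in flanks (13.3% against 21.2%). A candidate explanation is the base composition of the summits, whose G+C content was lower. Windows away from peaks, matched on G+C and position relative to start sites, carried the core in 13.5% ± 1.15 (SD over 10 draws), -0.165 percentage points from the summits, within the 3 points set for this explanation before these windows were drawn. The comparison with flanks may thus reflect composition, and the matched windows show neither a gain nor a loss of the core. The single group of samples gives no biological contrast, so no biological explanation was tested for this or the next patterns beyond the sites themselves.

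Ribosomal protein and glycolytic promoters stood out among bound genes. Housekeeping promoters as a class are argued against as the whole cause for ribosomal protein genes, since 0 of 4 other housekeeping lists passed and these had 10.6% of 188 genes bound, more than the 6.16% of other genes (exact p = 0.0209) but fewer than the 47.8% of ribosomal protein genes (exact p = 1.95e-11, and at most 2.13e-06 with the stronger 636 peaks or either replicate alone), although peaks at mRpS10, mRpL41, mRpL23 and eEF1gamma had been noticed before that test was set. Direct binding through the core stays open for ribosomal protein genes. Of their 44 peaks 16 carried it, against 14.0% of 643 other promoter peaks. The one-sided exact p of 0.00159 was for ribosomal protein and glycolytic peaks together (16 of 50). That test ignored G+C content, which was 45.5% at ribosomal protein peaks and 34.1% at other promoter peaks. Matched windows for the ribosomal protein peaks, a condition added after the test, had the core in 24.1% ± 6.17 (SD over 10 draws). Bound and unbound ribosomal protein start sites held it in 22 of 44 and 17 of 48 cases (exact p = 0.206). Of the 6 glycolytic peaks 0 carried it, which argues against binding through a core within 50 bp of these summits. Their matched windows had it in 10% ± 8.61 (SD over 10 draws), so no loss was shown. For glycolytic genes the housekeeping class stays open. Their 6 of 17 differed from these lists with the reported peaks (exact p = 0.0109). So did the 6 of 17 with replicate 1 alone, with Tpi in place of Eno (exact p = 0.0025). Tpi lies close to sima, and its signal was not separated from any extra copies on the transgene. The share did not differ among the stronger peaks (3 of 17, exact p = 0.0806) or with replicate 2 alone (4 of 17, exact p = 0.25). Enrichment at highly transcribed genes whatever the tagged protein cannot be told apart from binding by Sima, since no untagged sample was analysed here; the share of 290 tRNA genes with a summit within 500 bp was 2.07% against 0.953% ± 0.743 after shifts (permutation p = 0.226), no detectable excess, which decides nothing for genes of another class.

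Regions were denser over sima than over the genome, 53.6 against 22.4 per 100 kb. Of the 322 genes of 0.67 to 1.5 times its length, 4.97% held as many pooled regions as its 34 (Wilson 95% interval 3.08 to 7.92%). A high count does not separate extra sima copies on the transgene from binding of Sima at its own gene, so these cannot be told apart, and the extent of the sequence on the transgene is not given in the sources used here.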
